A study of Mus musculus with 4 samples.

How the data were processed

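DNase-seq, which maps open chromatin by sequencing the ends of DNA that the nuclease DNase I cuts, was run on lymphoid tissue inducer (LTi) cells, a group 3 innate lymphoid cell type that induces lymph nodes and Peyer's patches. The cells came from Peyer's patches of 2 groups of C57BL/6 mice, with 2 libraries each. Controls carried intact Tcf7, the gene for the transcription factor TCF-1, and the Tcf7-KO mice carried a floxed Tcf7 together with a Cre recombinase. Per the labels' protocols, each library started from 300 sorted cells, gated on CD127 and CCR6 and on the absence of lineage markers, KLRG1, NK1.1 and NKp46, which were digested with 0.3 U of DNase I for 5 minutes.

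The data analysed here are 1 table for the whole series. Per the submitters' processing notes, Bowtie2 2.4.2 and SICER 2.0 were used with genome build mm10. SICER joins neighbouring enriched 200 bp windows into broad islands, and the islands are treated here as accessible regions. Per the file headers, each island has a position, a read count on the peak side, a read count on the control side, a p-value, a fold change and an FDR. The authors deposited the read counts without normalization. The fold is the authors' deposited ratio of peak-side reads to control-side reads after the latter are multiplied by 1 factor, 0.345, in every island, with 0.25 reads in place of 0. The deposited p-values are the upper tail of a Poisson distribution around the scaled control-side reads, and the deposited FDR (q-value) ranks them over the islands of the table. All 16584 folds and p-values were recomputed from the 2 read columns (relative tolerance 1e-06 for the fold, absolute tolerance 1e-06 for p), as was the FDR within 0.01. The table is not filtered on FDR.

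No header or label says which libraries stand on the peak side and which on the control side, or whether replicates were pooled. "Control" in the header can mean the background input of the peak caller or the control mice, although no library is labelled as an input. Neither column was therefore given to a genotype, values per library were not used here, and control and Tcf7-KO mice are not compared. The planned models of counts per library, with their replicate spread, leave-one-out fits and gene set tests, were not run, and the islands are described instead, as the design fixed before the data were examined provides. Statements on the fold compare the reads of the 2 sides of the table, not 2 conditions. The library totals are not given in the sources used here. The factor of 0.345 puts the control side at 2.90 times the size of the peak side.

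Each fold below is peak-side reads over scaled control-side reads, with an exact (Clopper-Pearson) 95% counting interval from the 2 read counts. These intervals cover counting error only, since there are no replicate values, and reads without molecular identifiers are not independent molecules. The authors' deposited FDR takes the scaled control-side reads as known, so an island can be called while its counting interval reaches below 1. Over islands, the median ratio of the upper to the lower bound was 3.75. An island is called here when its FDR in the authors' deposited table was under 0.05. Coordinates are 1-based mm10 positions.

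Genes came from a RefSeq table of GRCm38.p6, the assembly that mm10 names, with 21900 protein-coding genes. It gives gene positions without strand, so transcription start sites could not be placed. Islands were assigned to the nearest end, of either kind, of a protein-coding gene within 50 kb, and an island within 1 kb of a gene end was called a gene-end island. This departs from the planned rule, which used start sites. No genome sequence was used, so motif content and GC content were not analysed. The 17 gene lists, with 312 genes (7 of them on more than 1 list), were written before the data were examined, and all 312 symbols matched the gene table. For each list, the number of genes with an island was set beside 10000 random lists of protein-coding genes matched on gene length in 10 classes. The ranges were recomputed under each gene assignment, a step added after seeing the data. The median fold was set beside 10000 random sets of islands matched on peak-side reads. These are descriptions of this table and give no p-value. The placement of islands near gene ends was compared with 1000 circular shifts of all islands along their chromosomes.

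The islands named in the text follow a rule fixed before the data were examined, adapted to a table without values per library. It takes every island of Tcf7 and 50 kb on either side. It takes the 12 largest folds among called islands, and the 10 smallest folds under 1, within the upper part of islands by reads (at or above the median). In each list it takes up to 4 called islands with the lowest FDR. The planned rule ranked by the test and by separation of replicates, and size was used for the smallest folds because the deposited p is 1 for every fold under 1. Lta, Ltb, Lef1, Myc and Axin2, and list genes named without a fold were chosen after their values were seen. Some items that this rule names, and results that rest on them, are not reported here. Pooled folds sum the reads of all islands assigned to a gene, and stand for list genes with more than 1 island, a choice made after their values were seen. A gene said to have no island has none assigned to it, while one assigned to a neighbouring gene can lie within it. The gene-end difference has a bootstrap interval from 2000 draws of islands. The alternatives tried were other FDR thresholds, other scalings of the control side, a read minimum, other gene windows, and leaving out chromosomes X and Y, mitochondrial DNA and islands over 200 reads. On simulated reads for the 16584 islands, the recomputed Poisson test recovered 80.0% of islands given a fold of 3 and 51.0% of those given a fold of 2. It called 0.72% of unchanged islands. Most simulated islands were unchanged and none were selected on the peak side, unlike those of the table. These rates therefore check the code and are not error rates of the authors' deposited calls. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1 were used.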

Results

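Chromatin accessibility was profiled by DNase-seq in LTi cells from Peyer's patches of 2 control and 2 Tcf7-KO libraries. The series was designed to ask how loss of TCF-1 affects accessible chromatin in these cells. The table analysed here holds 16584 islands with 1 read count on a peak side and 1 on a control side, and no label ties either side to a genotype. The following values therefore describe the accessible regions of the table and the ratio between its sides, and the difference between genotypes was not analysed here.

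The accessible regions lay mostly at the ends of genes. The islands covered 34.2 Mb, with a median width of 1800 bp (interquartile range 1200 to 2600). They held 425134 reads on the peak side and 645087 on the control side. The median island had 18 peak-side reads (interquartile range 12 to 27) and 27 control-side reads (16 to 44). The lowest peak-side count was 8, so a gene without an island is not shown to be closed. Of all islands, 9236 (55.7%) lay within 1 kb of an end of a protein-coding gene, 4034 (24.3%) lay elsewhere within a gene and 3314 (20.0%) lay between genes. After circular shifts of the islands, a mean of 6.14% lay at a gene end, and the highest of 1000 shifts reached 9.33%. Of 21887 protein-coding genes outside mitochondrial DNA, 10762 (49.2%) had at least 1 island within 50 kb and 8851 (40.4%) had a gene-end island.

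Tcf7, the gene targeted in the Tcf7-KO mice, lies on chromosome 11 (52246527 to 52283383). It and 50 kb on either side held 8 islands with 136 and 177 reads and a pooled fold of 2.23 (1.77 to 2.80), and 6 of the 8 were called in the authors' deposited table. The island over the Tcf7 gene end (52282401 to 52284800) had 19 and 38 reads and a fold of 1.45 (0.790 to 2.58), and it was not called. Within the gene, islands at 52265601 to 52267200 and 52278401 to 52281600 had folds of 3.96 (1.70 to 9.52) and 2.90 (1.32 to 6.37). Between genes, islands at 52297201 to 52298200, 52314201 to 52314800 and 52318001 to 52319200 had folds of 2.32 (0.992 to 5.31), 2.68 (1.12 to 6.36) and 4.67 (2.51 to 8.94). The 2 islands on the far side, assigned to Skp1, had folds of 1.38 (0.581 to 3.06) and 1.51 (0.883 to 2.53). The intervals of 7 of these islands overlap each other widely at 10 to 24 reads, and these values do not check the genotype of either side.

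**Figure D1:**
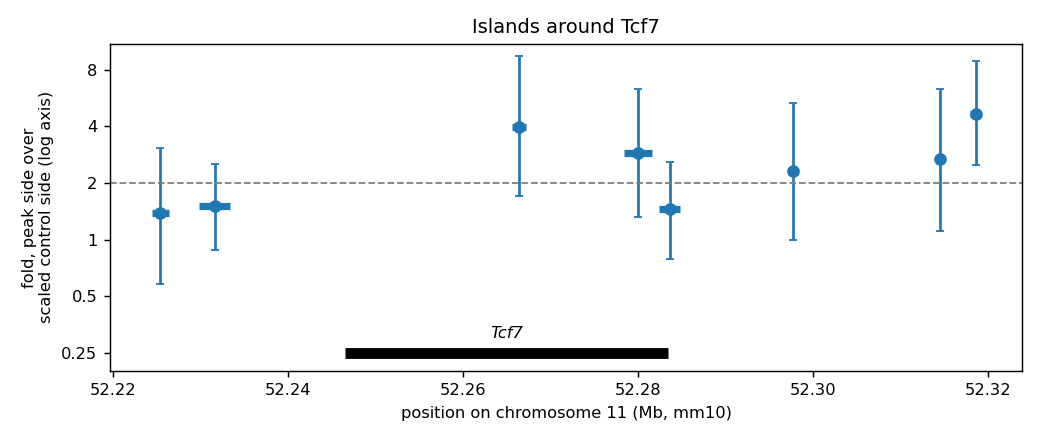
Folds of peak-side over scaled control-side reads (vertical log axis, points with 95% counting intervals, thick bars the island's extent) along mm10 positions in Mb around Tcf7, with a black bar for the gene and a dashed line at the median fold of all islands, 2.01. The 8 islands lie on both sides of the median, with the highest at 4.67.

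The identity genes of LTi cells and other group 3 innate lymphoid cells were among those with islands. Of 20 such genes, 18 had an island within 50 kb, where length-matched random lists had a median of 11 (central 95% of lists 7 to 15, and so for the ranges given for other lists). Housekeeping genes exceeded random lists as well (19 of 20, random lists 5 to 14), so such an excess is not particular to identity genes. Kit, a stem cell factor receptor carried by LTi cells, had 4 islands with a pooled fold of 3.10 (2.29 to 4.18), all called in the authors' deposited table. The one over its gene end (chromosome 5, 75572801 to 75577200) had 38 and 26 reads and a fold of 4.24 (95% counting interval 2.51 to 7.27). Il1r1, the interleukin-1 receptor, had 7 islands with a pooled fold of 3.63 (2.78 to 4.75), and the one with the lowest FDR, within a gene (chromosome 1, 40243601 to 40244400), had 16 and 2 reads and a fold of 23.2 (5.46 to 208). An island within a gene, assigned to Rora (chromosome 9, 69339201 to 69341400), had a fold of 7.38 (3.56 to 16.4). Tnfrsf25, a TNF receptor family member, had 62 and 66 reads over its gene end and a fold of 2.72 (1.90 to 3.91). Il7r, Id2, Ahr, Nfil3, Tox, Cxcr5, Il23r and Runx3 also had islands. No island was assigned to Ccr6 or Cd4, but 19 of the 20 genes had one in the gene body or within 1 kb of it.

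Cytokine genes of LTi cells formed a further group. Of 15 genes, 12 had an island (random lists 3 to 11), and in the authors' deposited table all 12 had a called one. Of all 10762 genes with an island, 9214 had a called one, so this is not particular to cytokine genes. With gene-end islands alone 7 had one, within the range of random lists (2 to 10), as were the counts within 10 kb and in gene bodies. Tnfsf11, which encodes RANKL, had 4 islands with 81 and 62 reads and a pooled fold of 3.79 (2.69 to 5.36). Its gene-end island (chromosome 14, 78305201 to 78308800) had a fold of 4.35 (2.46 to 7.83). Il17a and Il17f, the interleukin-17 cytokines, had 2 islands each, with pooled folds of 2.90 (1.58 to 5.33) and 3.63 (1.93 to 6.88). The ones with the lowest FDR (chromosome 1, 20739401 to 20741200 and 20766601 to 20767800) had folds of 6.77 (2.44 to 21.5) and 10.6 (2.81 to 59.4), the latter on 11 and 3 reads. Lta and Ltb, the lymphotoxin subunits that LTi cells use to induce lymphoid tissue, had 1 gene-end island each, with folds of 1.85 (0.873 to 3.77) and 1.86 (1.19 to 2.88). An island within a gene, assigned to Lif, had 69 and 99 reads and a fold of 2.02 (1.46 to 2.78). Tnfsf4, Tnfsf15 and Cxcl2 had no island.

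Genes of the TCF-1 and Wnt pathway had islands at 16 of 19 (random lists 6 to 15). Rnf43 and Nkd1, feedback inhibitors of Wnt signalling, had folds of 3.44 (2.10 to 5.69, pooled over 2 islands) and 3.75 (1.90 to 7.53, 1 gene-end island). The corepressor gene Tle1 had 67 and 98 reads (fold 1.98, 1.43 to 2.73), and Lef1, Myc and Axin2 had pooled folds of 1.98 (1.33 to 2.90), 2.10 (1.53 to 2.86) and 2.49 (1.61 to 3.83). Lgr5, Dkk1 and Sox13 had no island.

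The lists for other innate lymphoid programs did not exceed random lists. In the list of type 1 innate lymphoid, NK and natural cytotoxicity receptor genes, 6 of 22 genes had an island, 1 fewer than the range of random lists (7 to 16). With gene-end islands alone 2 had one (random lists 5 to 14), while with islands at any distance 8 did, within the range (7 to 16). Tbx21, Ncr1, Ifng, Gzmb and Prf1, which encode T-bet, NKp46, interferon-gamma, granzyme B and perforin, were among those without. Islands were present near Klrb1c (3 islands, 86 and 146 reads, pooled fold 1.71, 1.29 to 2.25), Itga2 (11 and 3 reads, fold 10.6, 2.81 to 59.4) and Il18r1 (pooled fold 3.97, 2.36 to 6.79). In the list of group 2 innate lymphoid cell genes, 6 of 15 had an island (random lists 4 to 12). Gata3, a transcription factor that is not restricted to that lineage, had 3 called islands in the authors' deposited table, with 93 and 100 reads and a pooled fold of 2.70 (2.01 to 3.61). Klrg1 had 2 islands with a pooled fold of 2.99 (1.80 to 4.98), and Il2ra had 3 with 37 and 43 reads.

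The lists of markers of other cells that a sort from Peyer's patches could hold lay within the range of random lists. The T cell list was below it in gene bodies (6 genes, random lists 8 to 16), as was the epithelial and stromal list with gene-end islands alone (4 genes, random lists 5 to 13). Of 20 T cell genes, 7 had an island (random lists 7 to 15), and Cd3e, Cd3g, Cd5, Cd8a, Cd28 and Bcl11b had none. Cd3d (17 and 17 reads, fold 2.90, 1.39 to 6.04), Cd6 (fold 3.69, 1.56 to 8.99) and Lck (3 islands, 36 and 51 reads, pooled fold 2.05, 1.30 to 3.20) had called islands in the authors' deposited table. Of 18 B cell genes, 7 had an island (random lists 5.98 to 14), and Ms4a1 and Cr2 had none. Blk, a Src-family kinase of B cells that some other lymphocytes share, had 6 islands with a pooled fold of 2.37 (1.83 to 3.05). Spib and Ebf1 had folds of 2.90 (1.51 to 5.58) and 6.53 (1.82 to 29.0). The myeloid list had islands at 11 of 20 genes (random lists 5 to 14), with pooled folds of 2.44 (1.71 to 3.45) for Fcgr3, 2.64 (1.97 to 3.54) for Batf3, 1.90 (1.40 to 2.57) for Cebpb and 3.31 (1.52 to 7.33, 16 and 14 reads) for Spi1. Csf1r, Itgam, Lyz2 and Adgre1 had none. The epithelial and stromal list had islands at 9 of 20 genes (random lists 6 to 15). They included Pecam1, Pdgfrb and Epcam, with pooled folds of 2.64 (1.69 to 4.13), 3.14 (1.73 to 5.72) and 1.53 (1.01 to 2.28), and Krt8 (1 island, fold 4.71, 1.81 to 13.1).

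The lists of activation, signalling, homing, cell cycle, survival and housekeeping genes lay above the range of random lists, those of homing and survival narrowly, since both lay within it under 10 kb, gene-end and gene-body assignment. Each of the 18 AP-1 and immediate early genes had an island (random lists 4 to 12). In the authors' deposited table each had a called one, as did 9214 of all 10762 genes with an island. The median island of this list held 40 peak-side reads. Ier2 had 107 and 145 reads (fold 2.14, 1.65 to 2.77), Nr4a3 had 104 and 149 reads (fold 2.02, 1.56 to 2.62), Fosl2 had 87 and 115 reads (fold 2.19, 1.64 to 2.92) and Nr4a1 had 4 islands with 144 and 195 reads (pooled fold 2.14, 1.71 to 2.67). The NF-kB and TNF receptor signalling list had islands at 17 of 18 genes (random lists 6 to 14), among them Tnfaip3, a brake on NF-kB, with a pooled fold of 2.58 (1.94 to 3.42), Map3k14 at 1.98 (1.46 to 2.65) and Nfkb2 at 2.05 (1.47 to 2.85). Of 23 cytokine receptor and STAT genes, 19 had an island (random lists 8 to 17). Socs1 and Stat5a had folds of 2.28 (1.76 to 2.95, pooled) and 3.38 (2.12 to 5.44), and Tgfbr2 had 7 islands with a pooled fold of 2.85 (2.17 to 3.74). Of 18 homing genes, 14 had an island (random lists 5 to 13), led by Gpr183, an oxysterol receptor that guides lymphoid cells, with 4 islands and a pooled fold of 3.05 (2.29 to 4.07). Ccr7 and Itga4 had pooled folds of 2.67 (1.76 to 4.05) and 2.54 (1.57 to 4.10). The memory and stem-like list had islands at 15 of 16 genes (random lists 5 to 13), including Ets1, Zeb1 and Bcl2, which had pooled folds of 2.13 (1.65 to 2.73), 3.08 (1.86 to 5.11) and 2.42 (1.83 to 3.18). The cell cycle list had islands at 17 of 20 genes (random lists 6 to 15), among them Cdk4 at 2.97 (1.88 to 4.72), Ccnd2, Cdk6 and Cdkn1a. The apoptosis list had 14 of 17 (random lists 5 to 13), with Bcl2l11 at 1.89 (1.44 to 2.48), Bcl2l1 and Fasl among them. The housekeeping list had 19 of 20 (random lists 5 to 14), with Actb at 107 and 181 reads (fold 1.71, 1.34 to 2.19), Pgk1, Hprt and Eef1a1 among them.

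**Figure D2:**
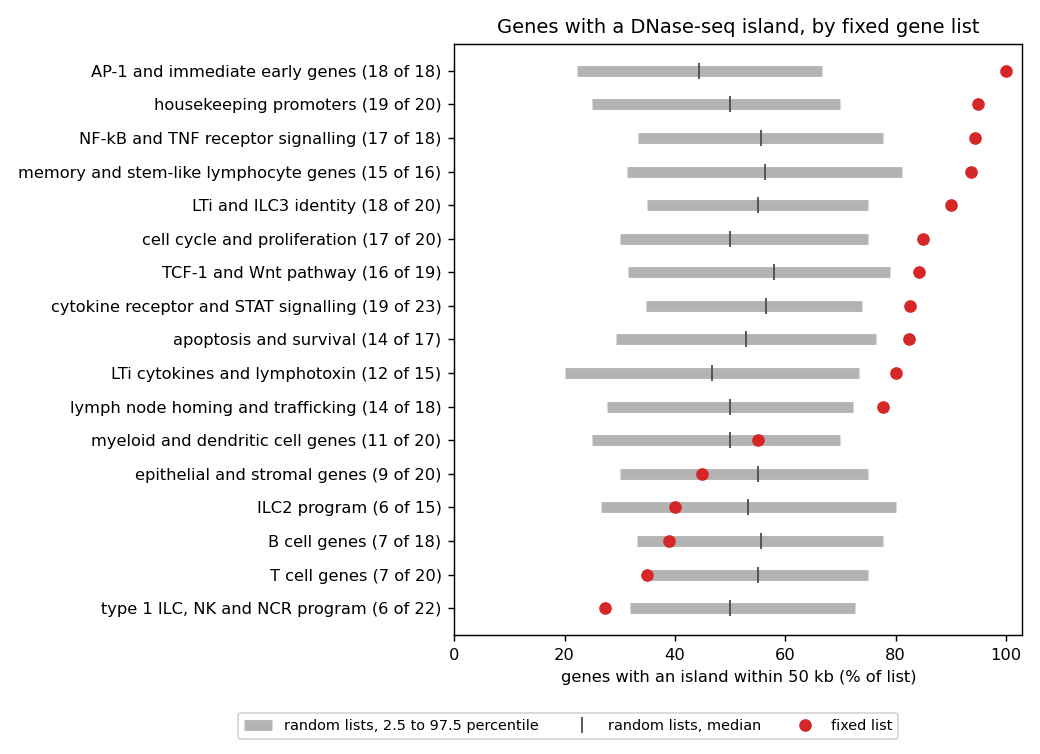
For each fixed gene list (1 per line, with the number of genes that had an island), the horizontal axis gives the percentage of its genes with an island within 50 kb: red points are the list, grey bars the central 95% and ticks the median of 10000 length-matched random lists. In 11 lists the point lies above the bar, in 5 within it, and in 1, type 1 innate lymphoid and NK genes (6 of 22), below it.

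Over the 17 lists, 219 of 312 genes had an island. The number of genes with an island lay above the range of random lists in 11 lists, within it in 5 and below it in 1, and 8 lists lay above it with gene-end islands alone. The median fold of a list's islands lay above that of random islands with as many reads in 3 lists, namely LTi and ILC3 identity (2.44, random 1.77 to 2.25), the TCF-1 and Wnt pathway (2.30, random 1.74 to 2.27) and B cell genes (2.57, random 1.60 to 2.55). It lay within the random range in the other 14. With so many lists, chance alone can place single lists outside a 95% range, and the latter 2 of the 3 lie close to its upper bound. The random islands were matched on peak-side reads, but not on location or on the number of islands per gene. With only the island of most peak-side reads per gene, the 3 medians were 2.36, 1.93 and 2.74. No random range was computed for these.

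Nearly every island had more peak-side than scaled control-side reads. The median fold was 2.01 (interquartile range 1.61 to 2.62), 16307 islands had a fold over 1 and 277 (1.67%) a fold under 1. The authors' deposited table has 13650 islands (82.3%) with an FDR under 0.05. When the control side was scaled by the reads in all islands instead, 1524 islands passed and the median fold was 1.05. That scaling sets the pooled fold of all islands to 1 by construction, so lower folds and fewer calls were built in. The level of every fold and the number of called islands thus rest on the scaling. Reads on both sides followed each other across islands (Spearman rho 0.837 over 16584 islands, which are not independent replicates). Among called islands at or above the median read count, the 12 largest folds ran from 7.46 to 10.4. They included islands within genes assigned to Ret (21 and 6 reads, 10.2, 3.96 to 30.7), Tmtc4 (18 and 5 reads, 10.4, 3.74 to 36.0), Cnksr3 and Itm2b (8.70 each, 3.31 to 26.8), Tox2 and, lying within the neighbouring Myo5c, Gnb5 (7.46 each, 2.97 to 21.1). Others lay at or near Casr (7.87, 3.17 to 22.2), Krtap6-2 (7.83, 3.67 to 18.1) and Dkk3 (7.61, 3.24 to 19.9), and 3 had no gene end within 50 kb.

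The smallest folds among islands at or above the median read count included a group on chromosome 1. Among the 10 smallest of these, 4 lay in a stretch of that chromosome around Ugt1a1 and Hjurp (0.620 to 0.763), and 1 each near Il31ra (0.734, 0.426 to 1.21) and Filip1l (107 and 411 reads, 0.755, 0.605 to 0.936). A further 3 had no gene end within 50 kb, one of them on chromosome 17 (39843001 to 39849800) with 3037 and 11347 reads and a fold of 0.776 (0.746 to 0.808).

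Gene-end islands had lower folds than other islands. The median fold was 1.86 (interquartile range 1.54 to 2.27) at gene ends, 2.34 (1.77 to 3.22) elsewhere within genes and 2.32 (1.74 to 3.19) between genes. The difference in median log2 fold, gene ends minus others, was -0.32 (95% bootstrap interval over islands -0.35 to -0.31). Gene-end islands also had more reads, with a median of 23 on the peak side and 37 on the control side, against 14 and 18 elsewhere within genes. With over 30 peak-side reads (2841 gene-end and 506 other islands) the difference was -0.012 (-0.043 to 0.033), so it was not detectable there.

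**Figure D3:**
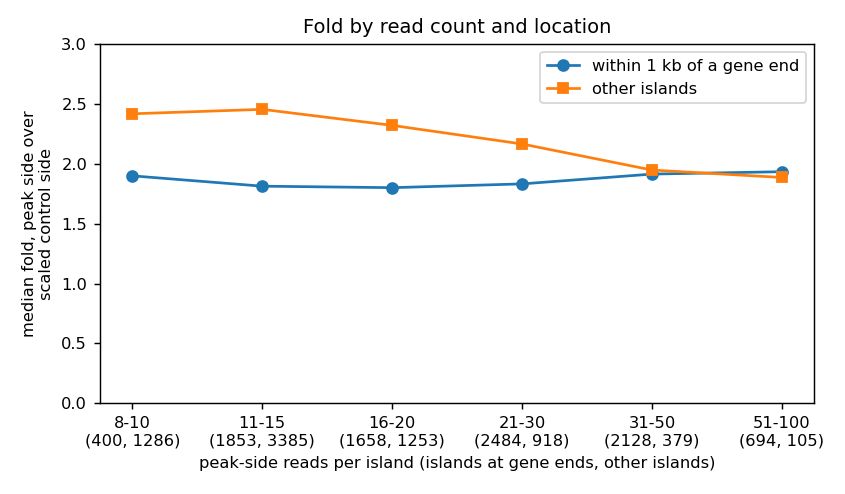
Median fold (vertical axis) of islands within 1 kb of a gene end (circles) and of other islands (squares) in classes of peak-side reads per island (horizontal axis, with the number of islands of each kind in parentheses). The medians are 1.81 and 2.45 at 11 to 15 reads and 1.91 and 1.95 at 31 to 50 reads.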

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

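Other scalings, FDR thresholds, read minimums, called islands alone, X and Y, high-read islands, gene bodies, an FDR under 0.01 and random ranges under each assignment for lists were chosen after seeing the data, many adapted from alternatives planned for the comparison of genotypes, while scaling at Tcf7, gene windows, reads per kb and the upper part by fold for the median fold (not for the gene-end share) were planned. The comparison of Tcf7-KO with control mice, with its leave-one-out fits, other models, cyclic loess, GC offset, motif content and gene set tests, was not run, since the columns are not tied to libraries. No paired analysis was possible because the columns carry no replicate numbers. The scaling of the control side moved every result it was run on. Scaled by the reads in all islands or by the median ratio, 1524 or 1097 islands passed in place of 13650, 7346 or 8286 had a fold under 1 in place of 277, and the median fold was 1.05 or, by construction, 1 in place of 2.01. Scaling by the reads in all islands put the pooled fold around Tcf7 at 1.17 in place of 2.23. It sets the pooled fold of all islands to 1 by construction, so lower folds and fewer calls were built into both scalings. A fold over 2 as well as the FDR left 8351 called islands. At least 20 reads left 6503, with 48 under a fold of 1, a median fold of 1.91 and 77.9% at a gene end in place of 55.7%. That share was 59.5% within 2 kb, 54.6% among called islands and 43.8% in the upper part by fold, whose median fold was 2.62 by construction. The gene-end difference in log2 fold of -0.32 was -0.012 above 30 reads. The correlation between the sides was 0.831 per kb in place of 0.837. The cause of these shifts was not tested except where construction is named. Leaving out X and Y, or mitochondrial and high-read islands, left 13443 or 13637 called islands and 267 or 274 with a fold under 1. No spread was computed for these 2 counts. The other values it was run on were unchanged or stayed within their spread. Of 102 alternative counts for single lists, 94 stayed within the binomial interval and 8 moved. With gene-end islands alone these were cytokine genes (7 in place of 12), type 1 genes (2 in place of 6) and epithelial and stromal genes (4 in place of 9). With an FDR under 0.01 in the authors' deposited table they were myeloid (6 in place of 11), epithelial and stromal (4), NF-kB (12 in place of 17) and housekeeping genes (14 in place of 19, and 20 in gene bodies). Against random lists, 8 lists lay above the range within 10 kb, 8 with gene-end islands alone, 8 in gene bodies, 11 at any distance and 10 with an FDR under 0.01, in place of 11. The lists that changed side under some assignment were cytokine, type 1, homing, apoptosis, T cell and epithelial and stromal genes. Over islands, the median ratio of the upper to the lower bound of a fold was 3.75.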

Other observations

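The tests of selection for the folds over 1, and of chance order, shared reads and copies for the run of low folds, were chosen after the result was seen, as were the gene families and neighbours named here. Of 81 ribosomal protein genes, 69 had an island within 50 kb (length-matched random lists 22 to 38), as did 31 of 39 proteasome subunit genes (14 to 26) and 54 of 78 mitochondrial ribosomal protein genes (28 to 44). Zinc finger genes named Zfp had islands at 253 of 397 (199 to 237), Hox genes at 22 of 39 (11 to 23) and solute carriers at 204 of 375 (193 to 231). Fewer genes than in random lists had an island among olfactory receptors, with 10 of 1106 (131 to 166), vomeronasal receptors, with 4 of 353 (84 to 112), and keratins, with 11 of 53 (18 to 32). The genes with the most islands were Nfatc1, an activation-induced transcription factor, with 11, and Runx3 and Ninj2 with 9 each. Runx3, which acts in lymphocyte development, had 169 and 219 reads and a pooled fold of 2.24 (1.82 to 2.75), and Nfatc1 had 213 and 284 reads and 2.18 (1.81 to 2.61).

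Islands around Hjurp formed a run of low folds. The 14 islands from Ugt1a1 to Trpm8 (chromosome 1, 88211801 to 88309600, 97.8 kb) had 444 and 1530 reads and a pooled fold of 0.842 (0.756 to 0.936), while the next islands on either side, at Atg16l1 and Glrp1, had 2.04 and 4.46. In all, 5 runs had a pooled fold under 1, where random orders gave a mean of 2.28 and at most 6. The highest pooled fold over 5 neighbouring islands, 5.12 from Ncoa3 to Prex1 on chromosome 2, was reached in 100 of 1000 random orders, so chance is not excluded for it. The 15 islands with over 200 peak-side reads took 13.4% of peak-side and 13.6% of control-side reads, and the largest (chromosome 2, 98666201 to 98667400) had 18039 and 20320. The 10 islands on chromosome Y had a median fold of 1.06 and those on X 2.14. On Y, 5 of the islands lay in 1 stretch of 71.6 kb (90737601 to 90809200). That stretch held 154 of the 218 peak-side and 447 of the 611 control-side reads on Y.

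For the Hjurp run, chance order is argued against, since its lowest 5 islands reached 0.714, which 0 of 1000 random orders matched. Reads shared between near-identical copies stay open. The median of 5.07 peak-side reads per kb lay at the 10.9th percentile of all islands, far under the 99th percentile of 49.3. However, a few copies need not give a high density, and the run was picked for a low peak side. More copies of this segment in the DNA on the control side stay open. The chi-square for 1 ratio of reads along the run lay at the 74.8th percentile of other runs of 14 islands. Most other runs were thus more even than this one, so the percentile cannot single out extra copies and decides nothing about them. By counting error alone unevenness along the run missed a threshold of 0.05 (chi-square 21.7, p = 0.0594, unadjusted). Missing that threshold does not show 1 ratio along the run. Broad accessibility on the control side would give similar reads and stays open, and no biological explanation was tested, since neither side was assigned to a genotype.

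For the median fold of 2.01, selection of islands on the peak side as the whole cause is argued against, since the 840 islands with over 50 peak-side reads still had a median fold of 1.92. A scaling factor off by the same amount everywhere may contribute: of the 824 islands with 51 to 200 reads, 90.8% (exact interval 88.6 to 92.7) had a counting interval that held their common median, where 1 shared fold predicts about 95%. A lower bound of 90% for a shared factor had been set before this value was seen, and the value lies above it. That its interval should also lie above the bound was required only after the value was seen, and it does not. The interval lies wholly below 95%, which argues against 1 shared fold with counting error alone for these 824 islands. Reads that are not independent molecules could also lower this share, so folds that vary between islands are not shown by it. A shared factor acting beside such spread stays open, and no biological explanation was tested.

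For the lower fold at gene ends, selection on the peak side may contribute, since above 30 reads the difference was -0.012 in log2 with an interval that reaches 0. The number of peak-side reads alone does not account for it: at equal reads gene-end and other islands had median folds of 1.81 and 2.45 at 11 to 15 reads, 1.80 and 2.32 at 16 to 20, and 1.83 and 2.17 at 21 to 30. Selection would need to act more strongly outside gene ends at the same read count, which was not tested. Without the high-read islands 100% of the difference was left, but so few islands hardly move a median, so this decides nothing about reads from repeats. Whether gene ends differ in accessibility between the sides stays open, and no biological explanation was tested.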
